A study of Mus musculus with 6 samples.

How the data were processed

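RNA was measured by sequencing in 6 whole grafts of the mouse melanoma line B16F10 grown in the tongue, 3 labelled as controls and 3 labelled as having the nociceptive nerves of the neck lymph nodes inhibited. The deposited table held raw read counts per Ensembl gene, 1 column per library, with no normalization by the authors visible in the values, which were whole numbers with a different total in each library. The genome build mm10 and the aligner HISAT2 2.0 were named per the submitters' processing notes; the counting program, the annotation release, the read filters and the strand setting were not given in the sources used here. How reads of overlapping genes, antisense partners and near-identical copies were assigned is therefore unknown, and such genes are given as uncertain. Every row of the table named a gene, and no column of per-sample values was left unused (0 columns).

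Columns were assigned to samples by their names. The column names of the treated group spoke of nociceptive denervation and the sample titles of nerve inhibition, and the group names used here follow the titles. Of 55487 gene IDs, 55141 were matched to a symbol; the other 346 carried 0.0575% of the counts. Coordinates and exon lengths were taken from GENCODE M21 on GRCm38, the assembly that mm10 names. Library totals were between 14477277 and 20972494 counts, so that 1 count was worth between 0.0476 and 0.0701 CPM. Pairs of libraries of the same group differed by a chi-square of 8.41 to 20.1 per degree of freedom and pairs across the groups by 11.2 to 43.4, so no library was a repeat of another. Control 2 was closer to inhibition 3 (11.2) than to control 1 (19.4).

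Genes were kept with filterByExpr by group (count minimum 10, total minimum 15), which left 15666, and scaled with TMM factors. The 3 inhibition libraries were compared with the 3 control libraries by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes are inhibition over control, on the log2 scale, with the standard error taken as the absolute log2 fold change divided by the square root of the quasi-likelihood F. Levels per library are CPM, counts scaled to a common library total with TMM factors. No covariate entered, because the labels named no batch. The labels did not say that the 6 samples came from separate animals, so p-values measure only the spread between these samples.

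A total of 48 gene lists for cell types, cell states and pathways were fixed before the data were examined, as were the groups, the test, the alternatives and the rule for naming genes. Of these, 45 lists had at least 5 tested genes and were tested with camera in limma 3.58.1, with the inter-gene correlation preset at 0.01 and adjustment over the 45 lists. The same lists were tested with the correlation estimated per list and with fry, whose directional p asks whether the genes move on balance in 1 direction and whose mixed p asks whether they move in any direction. For each list the members past the test were counted over all genes tested and adjusted over the list alone. The level of a list in a library is the mean log2 CPM of its tested genes (prior count 2), less the mean of the controls.

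Genes were named by a rule with 4 parts. The first took the 12 called genes of largest fold per direction, or all where fewer passed, with a mean of at least 1 CPM, groups that did not overlap and no predicted, clone or antigen receptor segment name, or, where fewer than 3 passed, the 5 genes of that direction with the smallest p under the same CPM and name rules. The second took up to 4 called genes of each list, or, for a list past camera without any, the 2 members with the smallest p, given as values. The third fixed Calcrl, Ramp1, Pdcd1, Cd274, Trpv1 and Calca, and the last fixed Pmel, Tyrp1, Dct, Acta1, Ckm, Krt5 and Krt13 as measures of tissue content. Gm11595 was called but fell outside the rule, and it is named because the calls were few. The Krtap family, the keratin genes Krt14, Krt10 and Krt4, and a few further genes in the closing part were chosen after their values were seen.

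The alternatives were RLE and upper-quartile factors, no filter and a stricter filter (1 CPM in every library of a group), limma-voom, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, a minimum absolute log2 fold change of 1, the muscle level of each graft as a covariate, and tongue muscle, epithelial and gland genes left out before scaling. The fit was tested on simulated counts for the 15409 genes its filter kept, with the library sizes and dispersions of this comparison of inhibition against control. It recovered 72% of 100 genes changed by a fold of 2 and 89% of 100 genes changed by a fold of 4, and it called 9 of 15190 unchanged genes. A shift of -0.4 placed in the hypoxia list was found by camera with the preset correlation and missed with an estimated correlation (adjusted p = 0.208), and 0 of the 43 lists other than hypoxia and glycolysis were called. The simulated genes were drawn independently, whereas the hypoxia list had an estimated correlation of 0.41 in the real data. The simulation therefore cannot tell how often the preset correlation gives false list calls here. Its counts were drawn from negative binomial distributions at the fitted gene dispersions, with no further variation between grafts. Its recovery holds for independent genes under that setting only and does not give the recovery in the real libraries. There edgeR called 0 of 26 tested skeletal muscle genes, whose median fold was 2.44.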

Results

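Whole-tissue RNA sequencing described 6 tongue grafts of B16F10, a pigmented melanoma line that grows in C57BL/6J mice. Viral vectors that travel backwards along axons had been injected into the cervical lymph nodes 6 weeks before the graft, so that nociceptive nerves reaching the nodes carried either a red fluorescent protein alone or the same protein with hM4D(Gi), a designed receptor that silences neurons when its ligand is given. The ligand deschloroclozapine was given 2 times per day for 12 days, after which the grafts were freed of surrounding tissue and their RNA extracted. Sample labels called the controls vehicle-treated, while the design text described both vectors with the ligand, so which of these the controls were remained unclear. The 3 control libraries held 16472276, 15420091 and 20914180 counts and the 3 inhibition libraries 14477277, 19225621 and 20972494. The manipulated nerves ran to the lymph nodes, and neither the receptor nor the fluorescent protein was counted, so the graft libraries gave no check of the manipulation itself.

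The comparison asked how the melanoma graft differed when the nociceptive nerves of the draining nodes were inhibited. Cxcl5, a chemokine that attracts neutrophils, fell from 10.3 ± 2.62 to 1.89 ± 0.252 CPM (SD, n = 3 per group), a log2 fold change of -2.44. Synpo2, an actin-binding protein of muscle Z-discs, rose from 15.2 ± 2.47 to 37.5 ± 4.05 CPM (log2 fold change 1.30). The keratin-associated proteins Krtap4-7, Krtap4-16 and Krtap4-2, structural proteins of hair and of hard keratin in the tongue, rose by log2 fold changes of 3.55, 4.01 and 3.62, and the predicted gene Gm11595 beside them rose by 3.61. These 6 genes, 5 higher and 1 lower, were all that passed at an adjusted p under 0.05 among 15666 genes, and in each of them the 3 libraries of 1 group lay above the 3 of the other.

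The edgeR adjusted p was 0.0334 for Cxcl5 (standard error 0.26), Synpo2 (0.14) and Krtap4-7 (0.39), and 0.0366 for Krtap4-16 (0.47), Krtap4-2 (0.44) and Gm11595 (0.44). On GRCm38, Cxcl5 (ENSMUSG00000029371) lies on chromosome 5 from 90759360 to 90761624, and Synpo2 (ENSMUSG00000050315) on chromosome 3 from 123076519 to 123236149. Krtap4-2 (ENSMUSG00000044649, 99634111 to 99635084), Krtap4-7 (ENSMUSG00000045109, 99643106 to 99644089), Gm11595 (ENSMUSG00000078668, 99771714 to 99772913) and Krtap4-16 (ENSMUSG00000046474, 99850655 to 99851608) all lie in 1 cluster on chromosome 11, each annotated as protein-coding. Control means in this cluster were 0.163 to 0.329 CPM, from 1 to 8 counts per library, against inhibition means of 2.15 to 4.40 CPM. Genes this similar can share reads, so the value of any single member is uncertain.

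**Figure D1:**
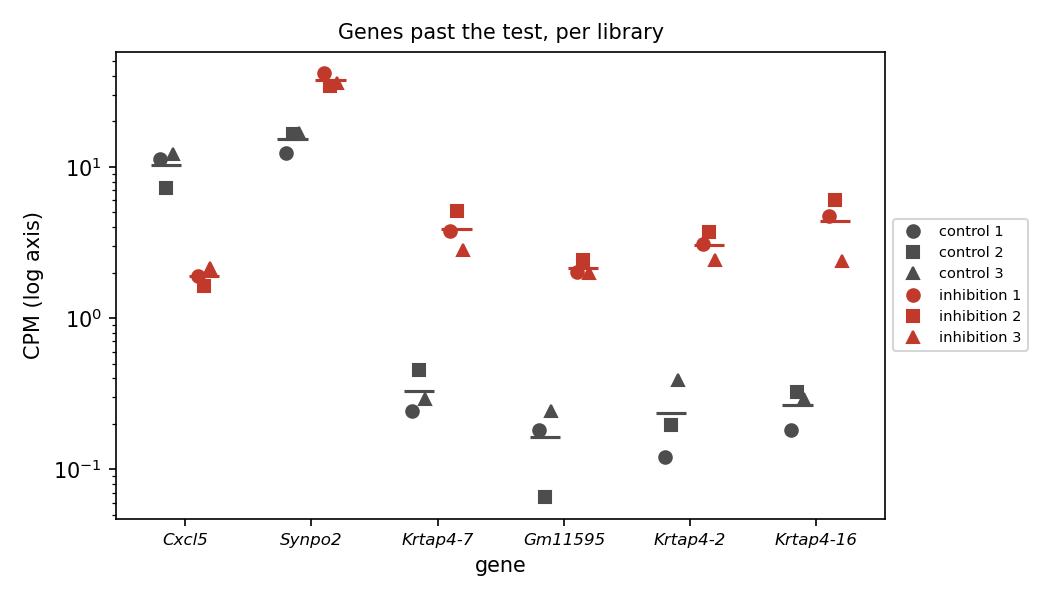
Level in CPM (log axis) of the 6 genes past the test in each of the 6 libraries; grey symbols are control and red symbols inhibition libraries, the symbol shape gives the replicate number and the horizontal lines are group means. Cxcl5 lay at 7.29 CPM or more in every control and at 2.14 CPM or less in every inhibition library, and the other 5 genes lay higher in every inhibition library.

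The number of calls depended on the test and on single grafts. DESeq2 called 553 genes (372 higher, 181 lower), all 6 of the edgeR calls among them, limma-voom called 0 with 1366 higher and 1064 lower at an unadjusted p under 0.05, and edgeR without the filter on low counts called 1187. Leaving out control 3, inhibition 1 or inhibition 2 left 0 edgeR calls (with 1094, 770 and 772 genes higher and 1094, 655 and 933 lower at an unadjusted p under 0.05), while leaving out control 1, control 2 or inhibition 3 gave 11, 24 and 217. At an unadjusted edgeR p under 0.05 there were 1310 genes higher and 1097 lower, 2407 in all where no change would give 783, whereas a regrouping with control 1, control 3 and inhibition 3 against the rest gave 1714. In 21.3% of the genes the groups did not overlap, against 10% by chance. Below Cxcl5, the 4 genes with the smallest p on the lower side did not pass in edgeR, while DESeq2 called all 4. For single genes the adjusted p of edgeR is given throughout. They were Hdc, which makes histamine (log2 fold change -2.20, adjusted p = 0.0666), Rps12-ps3, a copy of a ribosomal protein gene that can share reads with its parent (-0.66, 0.0671), Cxcl3, another neutrophil-attracting chemokine (-4.11, 0.0788), and Sec23a, a coat protein of secretory vesicles (-0.46, 0.0969).

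Lists of genes of neutrophils and of inflammatory myeloid cells fell in the inhibition grafts. Of 17 tested neutrophil genes, 15 had a negative log2 fold change, with a median of -1.63 (quartiles -2.76 to -0.73) and a camera adjusted p of 8.08e-12. With an estimated correlation the call was lost (adjusted p = 0.348 with an estimated correlation). Trem1, a receptor that amplifies neutrophil activation, stood at 3.16 ± 1.55 CPM in controls and 0.655 ± 0.0208 CPM under inhibition, and Fpr1, the formyl peptide receptor, at 1.72 ± 0.972 and 0.203 ± 0.132 CPM. Neither passed over all genes (adjusted p = 0.122 and 0.157). Adjusted over the list alone, 8 neutrophil genes were lower; over all genes tested edgeR called 0, with 10 lower at an unadjusted p under 0.05, and DESeq2 called 5 lower. The inflammatory myeloid list fell with a median of -0.73 over 16 genes (12 negative; camera adjusted p = 0.00063, and adjusted p = 0.348 with an estimated correlation). Its leading members were Acod1, which makes itaconate in activated macrophages (log2 fold change -2.48, adjusted p = 0.122), and the cytokine gene Il1b (-2.88, 0.166). Adjusted over the list alone, 5 of its genes were lower and 1 higher, while edgeR called 0 over all genes tested, with 6 lower and 1 higher at an unadjusted p under 0.05, and DESeq2 called 4 lower. The inflammatory median was -0.45 without control 2, -0.39 with no filter and -0.43 with limma-voom. With the muscle level of each graft as a covariate the inflammatory and neutrophil medians were both -0.41 and still past camera (adjusted p = 0.00760 and 0.00257). Among 27 chemokine ligands Cxcl5 was the 1 gene called by edgeR (DESeq2 called 4 lower and 2 higher), and 3 were lower and 1 higher adjusted over the list alone. The list as a whole did not pass (median -0.13, camera adjusted p = 0.161), though it did with the muscle covariate (-0.17, 0.00430) and with the replicate block (-0.14, 0.0248). Muscle genes, described next, were higher in the same grafts.

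Genes of skeletal muscle rose together. All 26 tested members had a positive log2 fold change, with a median of 1.28 (quartiles 1.10 to 1.51), a fold of 2.44, and a camera adjusted p of 5.34e-18 that became an adjusted p = 0.348 with an estimated correlation. The giant sarcomere gene Ttn stood at 133 ± 40.5 CPM in controls and 364 ± 73.5 CPM under inhibition, and the Z-disc gene Actn2 at 27.6 ± 9.12 and 70.9 ± 14.5 CPM, with adjusted p of 0.162 and 0.166. The 2 muscle genes fixed as measures of tissue content gave log2 fold changes of 1.11 ± 0.26 for Acta1 and 1.28 ± 0.60 for Ckm (standard errors; adjusted p = 0.186 and 0.393). There were 11 muscle genes higher adjusted over the list alone; edgeR called 0 over all genes tested, with 14 higher at an unadjusted p under 0.05, and DESeq2 called 8. The level of the list overlapped between the groups, at 0.70 in control 2 and 0.68 in inhibition 3, with 1.57 and 1.53 in inhibition 1 and 2 and -0.50 and -0.19 in control 1 and 3. Genes of muscle precursors and regeneration rose less, with a median of 0.40 over 11 genes, 8 of them positive (camera adjusted p = 0.00549, and adjusted p = 0.348 with an estimated correlation). The call was lost without inhibition 3 (adjusted p = 0.0525) and with the muscle covariate (0.136), where the medians were 0.43 and 0.34, and without control 1 the median was 0.20. Des, an intermediate filament gene of muscle that the muscle list also holds, had a log2 fold change of 0.90, and Chrna1, a subunit of the acetylcholine receptor, 1.02 (adjusted p = 0.171 and 0.206). Of these genes 4 were higher adjusted over the list alone, and edgeR called 0 over all genes tested against 1 in DESeq2, with 4 higher and 1 lower at an unadjusted edgeR p under 0.05.

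Squamous epithelium genes rose as well, 26 of 29 being positive, with a median log2 fold change of 0.77 (quartiles 0.38 to 1.52; camera adjusted p = 1.1e-06, and adjusted p = 0.517 with an estimated correlation). The level of this list overlapped between the groups (0.55 in control 2, 0.28 in inhibition 3). Flg, a cornified layer protein, stood at 0.244 ± 0.0565 CPM in controls and 2.35 ± 1.03 CPM under inhibition (log2 fold change 3.21, adjusted p = 0.0788), and Lor, another, at 17.7 ± 6.33 and 58.3 ± 29.9 CPM (1.72, 0.239). The basal keratin gene Krt5 had a log2 fold change of 0.43 ± 0.21, and Krt13, the keratin of the non-cornified mucosa, 1.08 ± 0.68 (standard errors; adjusted p = 0.389 and 0.497). Of further keratin genes examined outside the naming rule, Krt14 was lower (-0.23, adjusted p = 0.504). Krt10 (2.58, 0.250) and Krt4 (1.52, 0.443) were higher. A single epithelial gene (1 of 29) was higher adjusted over the list alone; edgeR called 0 over all genes tested, with 8 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 5 higher. With the muscle level of each graft as a covariate edgeR called 0 genes (194 higher and 324 lower at an unadjusted p under 0.05), and this list turned to a median of -0.40 and was called lower (camera adjusted p = 0.000359); the muscle level itself moves with the group. The 3 salivary gland genes that passed the count filter were too few to test as a list.

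Connective tissue genes rose too. All 25 fibroblast and matrix genes were positive, with a median log2 fold change of 0.63 (quartiles 0.48 to 0.80; camera adjusted p = 1.08e-19, and adjusted p = 0.348 with an estimated correlation). Col5a1, a fibrillar collagen, stood at 54.2 ± 5.98 CPM in controls and 84.4 ± 4.99 CPM under inhibition (adjusted p = 0.0766), and Acta2, smooth muscle actin, at 31.6 ± 3.55 and 46.1 ± 2.66 CPM (0.122). Of the 25 matrix genes, 22 were higher adjusted over the list alone; over all genes tested edgeR called 0, with 22 higher at an unadjusted p under 0.05, and DESeq2 called 14. With the muscle covariate the median was 0.17 and the list stayed past camera (adjusted p = 0.00464). Blood vessel genes rose with a median of 0.39, 18 of 20 being positive (camera adjusted p = 0.000233, and adjusted p = 0.517 with an estimated correlation), and this call was lost without inhibition 3 (adjusted p = 0.0716, median 0.23), while without control 1 the median was 0.17. The pericyte gene Rgs5 had a log2 fold change of 0.77 and the endothelial receptor Tie1 0.34 (adjusted p = 0.250 and 0.242). TGF beta targets rose with a median of 0.15 over 22 genes, 15 of them positive (camera adjusted p = 0.0124, and adjusted p = 0.366 with an estimated correlation; 0.0601 without inhibition 3 and 0.216 with the muscle covariate, with medians of 0.11 and 0.10), led by the log2 fold changes of Ccn2 (0.61, adjusted p = 0.162) and Tgfb3 (0.61, 0.181). Axon guidance and neurotrophin genes rose with a median of 0.34, 32 of 37 being positive (camera adjusted p = 0.000157, and adjusted p = 0.366 with an estimated correlation), with Plxna2 at 0.79 and Slit3 at 0.58 (adjusted p = 0.186 and 0.188). The axon guidance median was 0.16 without control 1. Under the muscle covariate it was 0.14 and the call was lost (adjusted p = 0.182). Higher when adjusted over the list alone were 0 vessel genes, 2 TGF beta targets and 0 axon guidance genes. In edgeR 0 of them passed over all genes tested, with 6, 5 and 10 higher at an unadjusted p under 0.05, and DESeq2 called 3, 4 and 1.

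**Figure D2:**
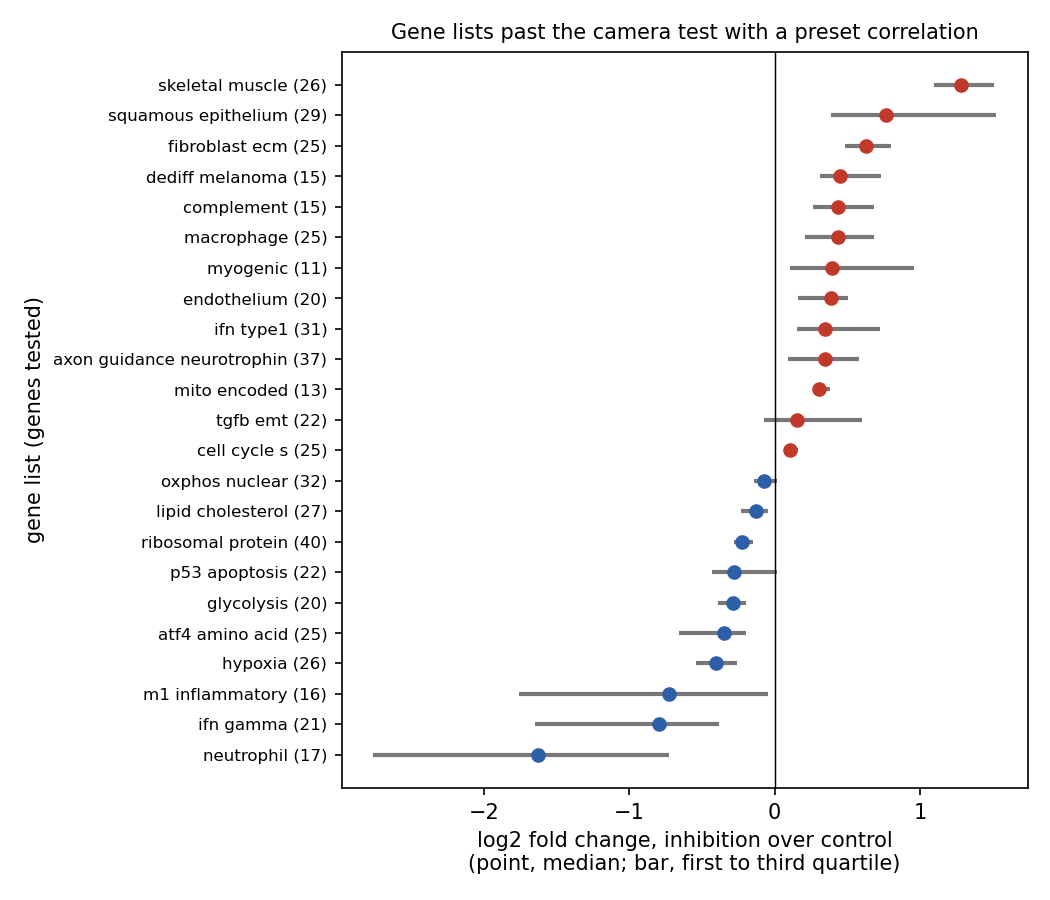
Median (point) and lower to upper quartile (bar) of the log2 fold change, inhibition over control, of the tested genes of the 23 lists past camera with the preset correlation; red marks lists called higher and blue lists called lower, with the number of tested genes in brackets. Skeletal muscle stood at 1.28 and the neutrophil list at -1.63.

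Monocyte and macrophage genes went the opposite way from those of neutrophils. Of 25 tested, 21 were positive, with a median log2 fold change of 0.43 (quartiles 0.21 to 0.68; camera adjusted p = 0.000251, and adjusted p = 0.517 with an estimated correlation). Csf1r, the receptor of macrophage colony-stimulating factor, stood at 17.9 ± 4.33 CPM in controls and 27.5 ± 2.93 CPM under inhibition (adjusted p = 0.186). Cd14, a receptor for bacterial lipopolysaccharide, ran against its list, with 16.3 ± 3.74 and 5.44 ± 1.64 CPM (log2 fold change -1.57, adjusted p = 0.0969). In this list 1 gene was lower and 0 higher adjusted over the list alone; over all genes tested edgeR called 0, with 7 higher and 1 lower at an unadjusted p under 0.05, while DESeq2 called 3 higher and 1 lower. The macrophage level overlapped between the groups (0.45 in control 2, 0.40 in inhibition 1), and the median was 0.26 without control 1 and 0.77 without control 2. The rise moved with the muscle genes: with the muscle covariate the median was -0.00534 and the call was lost (adjusted p = 0.735). Complement genes, 4 of which the macrophage list also holds, rose with a median of 0.43, 14 of 15 being positive (camera adjusted p = 0.000138, and adjusted p = 0.517 with an estimated correlation). C3ar1, the C3a receptor, had a log2 fold change of 0.68 and the inhibitor gene Serping1 0.69 (adjusted p = 0.186 and 0.218). No complement gene (0) passed adjusted over the list alone, as over all genes tested in edgeR, with 6 higher at an unadjusted p under 0.05 and 3 called higher by DESeq2. The complement level overlapped between the groups (0.35 in control 2, 0.28 in inhibition 3), and the median was 0.26 without control 1. With the muscle covariate it turned to -0.0679 and the call was lost (adjusted p = 0.326).

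Hypoxia response and glycolysis genes fell. Of 26 hypoxia genes 22 were negative, with a median log2 fold change of -0.40 (quartiles -0.54 to -0.26; camera adjusted p = 3.74e-14), and of 20 glycolysis genes 18 were negative, with a median of -0.28 (camera adjusted p = 4.43e-10). Both had an adjusted p = 0.348 with an estimated correlation, and the lists share 6 genes. Pgk1, a glycolytic kinase in both lists, stood at 3034 ± 289 CPM in controls and 2158 ± 232 CPM under inhibition, Eno1 (enolase) at 6969 ± 399 and 5314 ± 615 CPM, and Ak4, a mitochondrial adenylate kinase, at 69.1 ± 6.32 and 41.2 ± 9.43 CPM. Their adjusted p were 0.160, 0.167 and 0.166. There were 15 hypoxia and 12 glycolysis genes lower adjusted over the list alone; over all genes tested edgeR called 0, with 16 and 14 lower at an unadjusted p under 0.05, and DESeq2 called 12 and 6. The hypoxia level lay between -0.01 and 0.01 in the controls and at -0.69, -0.30 and -0.22 in the inhibition grafts. Given the muscle covariate, the hypoxia median was -0.23 and the glycolysis median -0.15, both still past camera (adjusted p = 3.36e-05 and 0.00252).

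Amino acid stress genes under the transcription factor ATF4 fell, all 25 being negative, with a median of -0.35 (camera adjusted p = 8.08e-12, and adjusted p = 0.437 with an estimated correlation). Without inhibition 1 the ATF4 median was -0.22. The serine synthesis genes Phgdh and Psph led, with log2 fold changes of -0.50 and -0.66 (adjusted p = 0.162 and 0.185). Ribosomal protein genes fell by little and in step, 39 of 40 being negative, with a median of -0.23 (quartiles -0.28 to -0.15; camera adjusted p = 1.36e-16, and adjusted p = 0.348 with an estimated correlation), including Rps14 at -0.41 and Rps18 at -0.30 (adjusted p = 0.143 and 0.163). All 13 protein genes of the mitochondrial genome were positive and the list rose, with a median of 0.31 (camera adjusted p = 3.04e-07, and adjusted p = 0.348 with an estimated correlation); mt-Nd2 stood at 0.53 and mt-Cytb at 0.33 (adjusted p = 0.162 and 0.166). Lower were 1 ATF4 gene and 26 ribosomal genes, and higher 8 mitochondrial genes, adjusted over the list alone. Over all genes tested edgeR called 0 of these, with 10, 29 and 9 at an unadjusted p under 0.05, and DESeq2 called 8, 13 and 4. Targets of p53 fell with a median of -0.28 over 22 genes, 16 of them negative (camera adjusted p = 0.00111, and adjusted p = 0.437 with an estimated correlation), with Phlda3 at -0.44 and Bbc3 at -0.69 (adjusted p = 0.186 and 0.218). Nuclear genes of the respiratory chain fell by a median of 0.07 on the log2 scale over 32 genes (camera adjusted p = 0.0152, and adjusted p = 0.716 with an estimated correlation), with Sdhb at -0.24 and Ndufv1 at -0.23 (adjusted p = 0.186 and 0.218), and this call was lost without control 3 (adjusted p = 0.298, median -0.0289) or inhibition 3 (0.118, -0.0491), and the median was -0.13 without control 2. With the muscle covariate the p53 median turned to 0.0619 and both calls were lost (adjusted p = 0.590 for p53 targets and 0.544 for respiratory genes, at a median of -0.0265). The p53 level overlapped between the groups (-0.0986 in control 2, -0.0952 in inhibition 3). Adjusted over the list alone 0 p53 targets and 0 respiratory genes passed. In edgeR 0 passed over all genes tested, with 5 p53 targets and 4 respiratory genes lower and 1 p53 target higher at an unadjusted p under 0.05, and DESeq2 called 1 p53 target lower.

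Of the gene lists for the melanoma cells, that of dedifferentiation was called and that of pigment was not. The pigment list had a median log2 fold change of 0.21 over 23 genes and did not pass (camera adjusted p = 0.0929; limma-voom 0.0490), with 0 members at an unadjusted edgeR p under 0.05 and 0 called by DESeq2. Its median was 0.0290 without control 1 and 0.10 without inhibition 1, and it was called higher without control 3 (0.26, adjusted p = 0.00868). Adding the muscle covariate turned it to -0.17, called lower (adjusted p = 0.00790). The melanosome genes Pmel, Tyrp1 and Dct gave log2 fold changes of 0.27 ± 0.19, 0.37 ± 0.26 and 0.10 ± 0.10 (standard errors; adjusted p = 0.514, 0.528 and 0.646). Genes of the dedifferentiated melanoma state rose with a median of 0.45, 12 of 15 being positive (camera adjusted p = 0.00202, and adjusted p = 0.517 with an estimated correlation), with Egfr at 0.76 and Zeb1 at 0.70 (adjusted p = 0.226 and 0.227), genes that stromal cells express too. The dedifferentiation level overlapped between the groups (0.36 in control 2, 0.30 in inhibition 3). Its median was 0.27 without control 1 and 0.73 without control 2. Under the muscle covariate it turned to -0.0220 and the call was lost (adjusted p = 0.544). S-phase genes rose by a median of 0.10 over 25 genes, with Mcm2 at 0.23 and Uhrf1 at 0.18 (adjusted p = 0.305 and 0.322; camera adjusted p = 0.0259, and adjusted p = 0.716 with an estimated correlation). The S-phase call was lost without control 1 (adjusted p = 0.0976), control 2 (0.435), inhibition 1 (0.297, median 0.0612) or inhibition 3 (0.183) and with the replicate block (0.0696), and without control 3 the median was 0.16. The G2 and mitosis list, at a median of 0.04, did not pass (camera adjusted p = 0.225), though 2 settings called it higher. These were the muscle covariate (0.13, adjusted p = 9.66e-06) and the run without inhibition 2 (0.0699, 0.0149). Cholesterol and fatty acid synthesis genes had a median of -0.13 over 27 genes (camera adjusted p = 0.0405, and adjusted p = 0.752 with an estimated correlation), and without control 1 the median was 0.06 (adjusted p = 0.504), without inhibition 3 it was -0.07 (0.748), and without control 2 and control 3 it was -0.23 and -0.20. The lipid call was also lost with the stricter filter (adjusted p = 0.0543) and with the muscle covariate (0.830, median -0.0330). Stard4 stood at -0.45 and Dhcr7, against its list, at 0.23 (adjusted p = 0.423 and 0.320). Adjusted over the list alone 0 genes of these 5 lists passed, and 0 passed over all genes tested in edgeR or DESeq2, with 5 dedifferentiation, 2 S-phase, 2 mitosis and 1 lipid gene higher at an unadjusted edgeR p under 0.05.

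Interferon genes varied more between controls than between the groups. The interferon gamma list had a median of -0.79, 19 of 21 being negative (camera adjusted p = 0.0154, and adjusted p = 0.716 with an estimated correlation), but its level was 0.39, 1.27 and -1.66 in the 3 controls and -0.46, -0.26 and -0.89 under inhibition. Without control 2 its adjusted p was 0.912 with a median of -0.14, without control 1 it was 0.0692 and without inhibition 3 it was 0.131, while without control 3 the median was -1.33. The call was also lost with the stricter filter (0.05002, median -0.66) and limma-voom (0.192, -0.28), and with the muscle covariate the median was -1.92. The GTPase gene Tgtp1, which has a near-identical neighbour and is uncertain, stood at 5.99 ± 5.84 and 0.701 ± 0.466 CPM, and Irf1, an interferon-induced transcription factor, at 23.2 ± 12.7 and 11.4 ± 1.96 CPM (adjusted p = 0.318 and 0.362). The type I interferon list had a median of 0.34, 26 of 31 being positive (camera adjusted p = 0.00566, and adjusted p = 0.716 with an estimated correlation; 0.0878, 0.298 and 0.195 without control 1, control 3 and inhibition 1), with medians of 0.20, 0.10 and 0.17 in these 3 runs, 0.91 without control 2 and 0.54 without inhibition 3. With the muscle covariate the type I list turned to a median of -0.92 and was called lower (adjusted p = 8.72e-32). Its leading genes were Ifi204 at 1.03 and Oas3 at 1.40 (adjusted p = 0.223 and 0.353). Adjusted over the list alone 0 genes of either list passed. In edgeR 0 passed over all genes tested, with 1 lower and 1 higher at an unadjusted p under 0.05 in the gamma and the type I list, and DESeq2 called 0 and 1. The class I and class II antigen presentation lists did not pass, with medians of -0.24 and 0.35 (camera adjusted p = 0.110 and 0.150). Class I was called lower with no filter (adjusted p = 0.0328), without control 3 (1.50e-07), without inhibition 1 (0.0461) and with the muscle covariate (5.56e-16). Its median was -0.48 without control 3, -0.75 with the muscle covariate, -0.12 with the replicate block, -0.0998 with limma-voom, -0.0977 without inhibition 3 and 0.0992 without control 2. Class II was called higher with limma-voom (0.0238), with the replicate block (0.0401) and without control 2 (5.47e-10) but lower with the muscle covariate (0.00790). Its medians in these settings were 0.63, 0.51, 0.96 and -0.69, and it was 0.16 without control 1 and 0.13 without control 3.

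Lymphocyte genes were close to the limit of detection. Of 24 T cell genes 5 passed the count filter, and the list did not pass (median -0.10 and mean 0.14, which differ in sign; camera adjusted p = 0.885). The regulatory and helper T cell list did not pass either, with a median of 0.17 while camera pointed lower (adjusted p = 0.980). Further, 2 cytotoxic and 3 natural killer genes were too few to test, and 18 untested cytotoxic genes together had 237 counts in the controls and 204 under inhibition. Pdcd1, which encodes PD-1, had 3, 23 and 4 counts in the controls and 1, 4 and 2 under inhibition and was not tested. Cd274, which encodes PD-L1, stood at 9.55 ± 2.96 and 7.001 ± 0.702 CPM (log2 fold change -0.44, adjusted p = 0.409). Of the receptor for the nociceptor peptide CGRP, Calcrl had a log2 fold change of -0.34 ± 0.20 and Ramp1 of 0.73 ± 0.63 (standard errors; adjusted p = 0.440 and 0.605). Trpv1, the channel that marks nociceptors, had 0, 0 and 1 counts in the controls and 0, 1 and 1 under inhibition, and Calca, which encodes CGRP, 1, 0 and 1 and then 0, 0 and 0; a difference in either was not detectable at this depth, where 3 counts correspond to between 0.143 and 0.210 CPM. The sensory neuron list, with 7 of 26 genes tested, did not pass (median -0.19, camera adjusted p = 0.533).

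**Figure D3:**
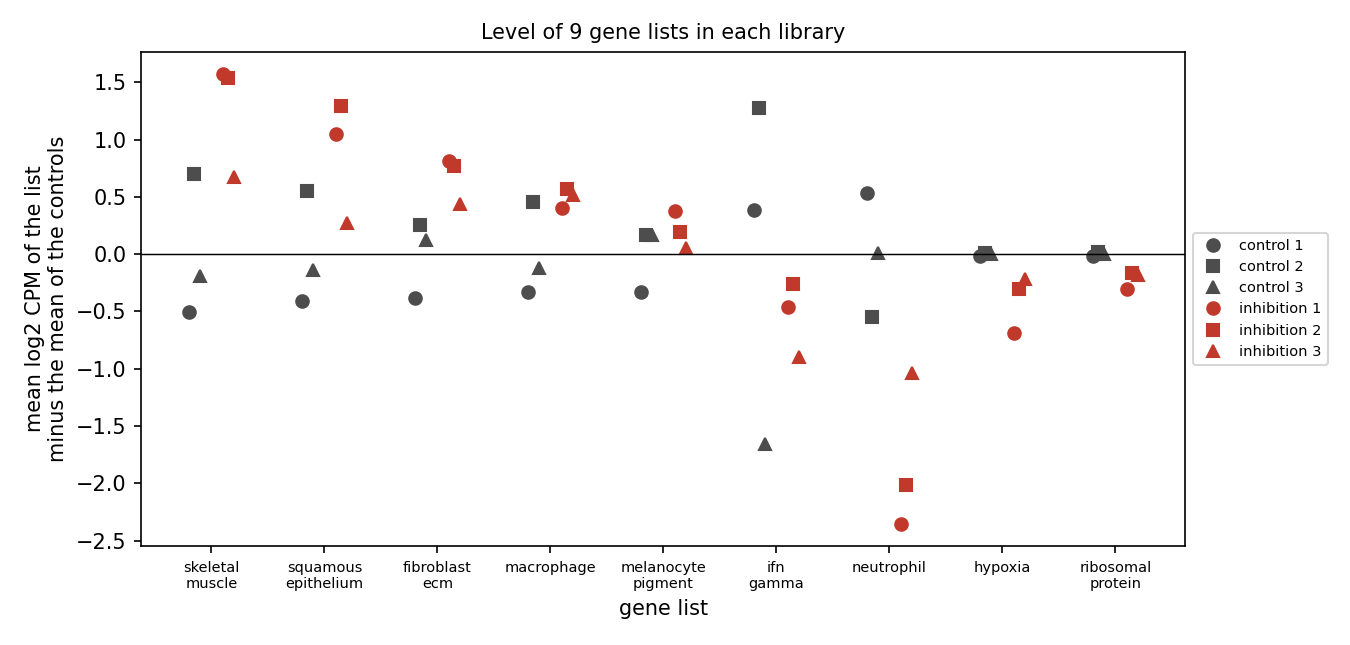
Level of 9 gene lists in each library, as the mean log2 CPM of the tested genes minus the mean of the 3 controls; grey symbols are control and red symbols inhibition libraries, and the symbol shape gives the replicate number. For the neutrophil, hypoxia and ribosomal protein lists all inhibition libraries lay below all controls, and for the fibroblast and matrix list all lay above. The interferon gamma level ran from -1.66 to 1.27 within the controls.

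In all, 23 of the 45 tested lists passed camera with the preset correlation, 13 higher and 10 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.348), as with fry (lowest adjusted p = 0.128, with 13 lists at an unadjusted fry p under 0.05) and fry mixed (0.0777). Of the 23 lists, 15 were also called in each of the 6 runs that left out 1 library.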

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

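The 5 genes higher and 1 lower were unchanged with RLE or upper-quartile factors, a stricter filter, tongue genes left out or a minimum log2 fold change of 1. With no filter 748 were higher and 439 lower, where the median prior degrees of freedom became infinite against 4.98 to 8.004 in the other edgeR settings. DESeq2 gave 372 and 181, limma-voom 0 and 0, and an adjusted p under 0.1 gave 26 and 7. Leaving out 1 library gave 0 to 170 higher and 0 to 47 lower; the cause was not tested. Of the 45 lists, 0 were called with an estimated inter-gene correlation, 0 by fry directional and 0 by fry mixed, against 23.

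With the replicate block 11 genes were higher and 3 lower, but 3 of the 6 calls were kept. Synpo2 (adjusted p = 0.0626), Krtap4-2 and Gm11595 (0.0684) were lost, while Hdc (0.0469) and Cxcl3 (0.0299) were gained. The block called 25 lists, with chemokine (0.0248), MHC class II (0.0401) and heat shock (0.0470) gained and S-phase (0.0696) lost. The inflammatory median was then -0.41, that of interferon gamma -0.42, and that of lymphoid structure changed sign (0.0554). Deviations of same-numbered libraries correlated at -0.18, 0.33 and 0.09, and those of other pairs across the groups at -0.39 to 0.30. With so few libraries these values neither showed nor excluded that the numbers pair the samples.

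With the muscle covariate 0 genes were higher and 0 lower. The covariate moves with the group and leaves 3 residual degrees of freedom. Standard errors grew and log2 fold changes stayed on their side, at 3.77 ± 0.75 for Gm11595 (3.61 ± 0.44 without the covariate), 3.11 ± 0.69 for Krtap4-2 (3.62 ± 0.44), 2.63 ± 0.54 for Krtap4-7 (3.55 ± 0.39), and 2.60 ± 0.59 for Krtap4-16 (4.01 ± 0.47). They were 1.07 ± 0.21 for Synpo2 (1.30 ± 0.14) and -1.79 ± 0.34 for Cxcl5 (-2.44 ± 0.26). Signs then turned for Ifi204 (-0.0905), Oas3 (-0.0246), Ramp1 (-1.30), Pmel (-0.19), Tyrp1 (-0.13), Dct (-0.0486), Ckm (-0.47), Krt5 (-0.17) and Krt13 (-0.78). Type I interferon (8.72e-32), squamous (0.000359), mast cell (0.000385), dendritic (0.000824), MHC class II and pigment (both 0.00790) were then past camera in the lower direction. Of the lists, the direction of the test turned for (medians in brackets) pigment (-0.17), dedifferentiation (-0.0220), T cell (-0.47), regulatory T cell (-0.0582), checkpoint (-0.0599), B cell (0.0567), dendritic (-0.26), mast cell (-0.52), MHC class II (-0.69), type I interferon (-0.92), lymphoid structure (0.0301), complement (-0.0679), squamous (-0.40), Schwann cell (0.0324), neuropeptide receptor (-0.00188) and p53 (0.0619). The median alone changed sign for macrophage (-0.00534), repair macrophage (-0.11), lymphatic (-0.0656) and unfolded protein (-0.24, past camera at 1.23e-07).

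Elsewhere the direction of the test of the regulatory T cell list turned with limma-voom (0.17) and tongue genes left out (0.16), that of the checkpoint list with no filter (-0.15) and that of the mast cell list with the stricter filter (0.55). Without 1 library, the sign of Dct turned (-0.000298 to 0.17), and ranges of medians for lists whose test turned were 0.00689 to 0.0719 for mitosis, -0.27 to 0.40 for T cell, -0.0152 to 0.34 for regulatory T cell, 0.0681 to 0.15 for checkpoint, -0.12 to 0.0618 for repair macrophage, 0.28 to 1.15 for mast cell, -0.48 to 0.10 for MHC class I, -1.33 to -0.14 for interferon gamma, -0.32 to -0.00894 for sensory neuron, -0.0587 to 0.0465 for unfolded protein and -0.23 to 0.0615 for lipid lists. The median alone changed sign for chemokine (-0.22 to 0.13), lymphoid structure (-0.12 to 0.54) and Schwann cell lists (-0.0350 to 0.12). It did so too for regulatory T cell (-0.14) and unfolded protein (-0.00410) with no filter. With the stricter filter it did so for repair macrophage (-0.0174), chemokine (0.0965), lymphoid structure (0.46) and neuropeptide receptor (-0.0855). With limma-voom these were chemokine (0.00175) and lymphoid structure (0.0963). Unfolded protein gave -0.000871 with tongue genes left out. The dendritic list was called higher by camera with no filter (median 0.37, adjusted p = 0.00528), with the stricter filter (0.38, 0.0215) and without control 2 (0.62, 0.000803). So were B cell genes with no filter (1.12, 0.0063) and heat shock genes without control 3 (0.19, 0.00903). Camera called lower the erythroid list without control 1 (-0.48, 0.009995) or inhibition 2 (-0.45, 0.0382). It did so for immediate early genes without control 3 (-0.27, 0.00265) or inhibition 3 (-0.20, 0.0136), and for unfolded protein genes without control 1 (-0.0506, 0.0381) or inhibition 2 (-0.0587, 0.0178).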

Other observations

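Beyond the fixed lists, 2 gene families were examined after their values were seen. All 20 tested Krtap genes, which encode the matrix proteins of hard keratin, were higher under inhibition, with a median log2 fold change of 3.40 (quartiles 3.05 to 3.57); 17 of them lie on chromosome 11. In edgeR 3 of the 20 were called and in DESeq2 19. The 9 hair keratin genes examined with them were all higher too, with a median of 3.60. The keratin genes Krt36 and Krt84 rose less than this median, by log2 fold changes of 1.996 and 2.10. Their control levels were 27.2 ± 10.2 and 22.7 ± 10.7 CPM, and their inhibition levels 108 ± 68.5 and 97.1 ± 56.3 CPM. Both passed in DESeq2 (adjusted p = 0.0357 and 0.0267) and neither in edgeR (adjusted p = 0.250 and 0.241). Ccr2, the receptor that brings monocytes into tissue, stood at 3.15 ± 2.19 CPM in controls and 9.65 ± 2.74 CPM under inhibition (log2 fold change 1.63, edgeR adjusted p = 0.220, DESeq2 adjusted p = 0.00221), while Cxcl2, a further neutrophil-attracting chemokine, stood at 18.4 ± 16.3 and 0.801 ± 0.505 CPM (-4.47, edgeR adjusted p = 0.186, DESeq2 adjusted p = 0.000272). Cxcl1 (-2.53), S100a8 (-3.02), S100a9 (-2.76) and Ly6c2 (2.04), examined beside them, passed in neither test (DESeq2 adjusted p = 0.0717, 0.226, 0.233 and 0.398).

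For the keratin and muscle pattern, the tests of a shared mucosa and of the inner root sheath without Tchh were chosen after the result was seen, and the test of hair follicle or fur was written before its values were examined. Muscle genes and hard keratin genes were higher in the same grafts. The Krtap median lay 2.63 above that of the other squamous genes, where a larger share of the same mucosa was taken to raise both alike. The Krtap family was picked for its rise, however, and Flg among the other squamous genes rose by 3.21. The test of a shared mucosa therefore decided nothing. The test of hair follicle or fur RNA pointed to hair, with root sheath genes at 32.7% to 37.1% of the Krtap level in the inhibition libraries (48.9% to 72.6% in the controls), but almost all of that came from Tchh, a gene that the filiform papillae of the tongue also express. The test was therefore repeated on the root sheath keratins alone, which reached at most 0.0837% in an inhibition library (3 counts against 3585 for the Krtap genes; at most 0.897% in a control, from 2 counts against 223). That outcome followed from the share of Tchh already seen, and no hair follicle sample gave a reference level. The counts gave no sign of an inner root sheath, but the repeat was no independent test against hair follicle RNA. A larger share of the same mucosa, hair or fur RNA and the nerve inhibition stay open. So does extra dorsal mucosa or muscle left at harvest, for which muscle genes alone could not give a test apart from the pattern itself.

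For the neutrophil pattern, all 3 tests were chosen after the result was seen. Plain dilution of the graft by tongue tissue was argued against by the melanocyte list, whose median was 0.21 where the neutrophil median was -1.63. A different makeup of the tissue was not tested by the melanocyte list. With the muscle covariate the neutrophil median shrank to -0.41 and the melanocyte median turned to -0.17. The neutrophil level was lowest in inhibition 1 and 2 (-2.35 and -2.01), where the muscle level was highest (1.57 and 1.53). An effect of control 1 alone was argued against by the neutrophil median of -1.59 without that library. A loss of myeloid cells as a whole was argued against, for the whole graft only, by the macrophage median of 0.43. That median was 0.26 without control 1 and -0.00534 with the muscle covariate. Macrophages of the tumour and of tongue tissue could not be told apart, so a loss within the tumour was not tested. The nerve inhibition itself, the makeup of the tissue, and a difference in tumour size or hypoxia, which no label gave, stay open.

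For the ribosomal and mitochondrial pattern, the test of gene length was written before its values were examined and that of pseudogenes was chosen after the result was seen. A bias by annotated exon length was argued against, because the ribosomal protein median was still -0.21 after a trend on that length was removed. The length merged all annotated exons of a gene, with 2394 bases for Rps14, and can exceed that of the transcripts present. A bias by transcript length was therefore not tested. Of 70 ribosomal pseudogenes 61 were lower as well, with a median of -0.29, which shared reads would also give, so this test decided nothing about them. Shared reads, a bias by transcript length, the nerve inhibition itself and the makeup of the tissue stay open.

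Regrouping the 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split is itself counted among the 10. By this count, 2 of 10 gave at least as many genes in the larger direction as the real 5 (highest other 7). At least as many in the smaller direction as the real 1 came from 1 of 10, the real split alone (highest other 0). At least as many lists as the real 23 were called in 4 of 10 (highest other 30).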
